A study of Mus musculus with 8 samples.

How the data were processed

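RNA was taken from whole ovaries of 8 superovulated female mice, and per the labels' protocols the libraries were made with a stranded kit that selects messenger RNA by its poly(A) tail. The groups and replicate numbers were read from the sample descriptions, 4 controls and 4 double knockouts (DKO), and no sample was left out. The labels give the strain as C57BL/6. The numbers in the sample titles were taken as animal numbers, which the labels do not state.

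The authors deposited 1 table of raw counts per library, made with featureCounts of Subread 1.5.2 per the file headers. Per the file headers, reads on exons were summed by gene ID with the strand setting for reverse-stranded libraries, on the RefSeq annotation of mouse assembly GRCm38.p5. The submitters' processing notes also list bcl2fastq 2.17.1.14, Trimmomatic 0.36 and 0.33, STAR 2.4.2a, edgeR 3.12.0 and the builds GRCm38.p3 and GRCm38.p5, with no order or role. The recorded command sets no option for reads that match several places, so values of genes with near-identical copies are uncertain. Each table held the same 41591 gene IDs. The values were whole numbers summing to 33145056 to 39257648 counts per library. Symbols came from a RefSeq table of assembly GRCm38.p6, used for names only, which matched 40290 IDs (96.9%), and coordinates are those of the count tables. The mitochondrial genes with rows in the count tables were those of ribosomal and transfer RNA, so their share of counts is no measure of mitochondrial messenger RNA.

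No pair of libraries within a group agreed within sampling noise, with a reduced chi-square of 25.05 to 143 over genes, so all 8 counted as separate replicates. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with tables prepared in Python 3.11.15. Genes were kept by the filterByExpr function of edgeR on the group, which left 16870. Principal components were taken on log2 CPM with a prior count of 2. Library sizes were scaled by TMM factors, which ran from 0.943 to 1.06. The test was edgeR's quasi-likelihood F-test with robust dispersion estimates and no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The biological coefficient of variation was 0.281. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are normalised with the TMM factors, except those of Ovgp1, Rn18s-rs5 and Rn7sk per library, which carry no TMM factor. For Insr, Igf1r and Pgr, CPM were also compared with an exact two-sided permutation test over the 70 assignments of samples to groups.

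Before the data were examined, 29 gene lists were fixed, covering LH-induced and cumulus expansion genes, luteal, steroid, lipid, glycolysis and hypoxia genes, insulin and FOXO signalling, proteases, cell cycle, apoptosis, clock, tight junction and immediate early genes, and markers of 12 kinds of cell or neighbouring tissue. For each, members called over all genes were counted, and again with adjustment over the list alone. Lists were tested with camera (preset correlation 0.01 and, beside it, an estimated correlation) and with fry, each adjusted over the 29 lists. Of these, 13 passed camera with the preset correlation and 0 with an estimated one.

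Named genes followed a rule fixed at the same time. It took Insr, Igf1r and Pgr, and then the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group, no overlap between groups and a named symbol. Of the 10 rises, 1 is not reported here, and no other gene took its place. The rule added up to 4 called members of each list, 14 genes of ovulation and steroid production whatever their result, and the member with the smallest adjusted p in lists with no call. Other genes named in the text were chosen after their values were seen.

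The script was tested on 3 simulated data sets drawn from the means, library sizes and dispersions of these samples, each with 200 changed genes among 16584 to 16616 tested. For 4 against 4 samples it recovered 17.9% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 96.5% of those changed 4-fold, and 6.45% of its calls were false. The changed genes all had means of at least 5 CPM, and genes were drawn independently, with no effect of run or library. Recovery of rarer genes, or in the presence of such effects, was not simulated. Alternatives covered 3 other scalings, 2 other filters, DESeq2, limma-voom with and without sample quality weights, non-robust dispersions, a test against 1.5-fold, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were a block for the run of animal numbers, animals 249 to 263 alone, and fits without control 1 and DKO 2 or without DKO 1 and DKO 2.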

Results

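Gene expression was measured by RNA sequencing in whole ovaries of 8 female mice, 4 controls and 4 mice with a conditional double knockout (DKO) of the insulin receptor gene Insr and the insulin-like growth factor 1 receptor gene Igf1r. The controls were littermates, labelled as wild type and positive for Cre recombinase driven by the progesterone receptor gene Pgr. All mice were about 3 weeks old and had been superovulated. They received 4 IU of equine chorionic gonadotropin, which drives follicle growth, and 48 h later 5 IU of human chorionic gonadotropin (hCG), which stands in for the ovulatory surge of luteinizing hormone (LH). Ovaries were taken 12 h after hCG, near the time of ovulation. The libraries held 33145056 to 39257648 counts in genes, with 35.6 ± 1.34 M (mega) counts in controls and 36.4 ± 2.53 M counts in DKO (mean ± SD, n = 4 each). Between 23313 and 24675 genes had a count above 0 in a library. The design implied 1 comparison, DKO against control, which addresses the genes that depend on insulin and IGF receptors in the ovary around ovulation.

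The targeted genes were examined first. Insr (gene ID 16337, chromosome 8, 3150922 to 3279649 in GRCm38.p5) was at 155 ± 10.3 CPM (counts normalised to library size) in controls and 126 ± 16.8 in DKO (mean ± SD, n = 4 each). The mean was 19.1% lower in DKO, with an exact two-sided permutation p of 0.0571 over the 70 assignments of samples to groups. Igf1r (gene ID 16001, chromosome 7, 67951833 to 68233668) was at 236 ± 28.6 CPM in controls and 214 ± 22.4 in DKO, 9.40% lower, with an exact permutation p of 0.371. In the model over all genes the log2 fold changes, DKO over control, were -0.30 ± 0.11 (SE) for Insr and -0.14 ± 0.12 for Igf1r, and neither passed the test (adjusted p = 0.226 and 0.639). Within the 5 ovaries whose sample titles carry the numbers 249 to 263, taken here as animal numbers, they were -0.12 and 0.014. These are counts over whole genes, in which a deleted exon cannot be separated, and a whole ovary also holds cells that do not express Pgr, so they check the genotype labels only weakly. Pgr itself (gene ID 18667, chromosome 9, 8893175 to 8968611), which LH induces in granulosa cells before ovulation, was at 4.86 ± 1.75 CPM in controls and 1.61 ± 0.537 in DKO (log2 fold change -1.59 ± 0.36, adjusted p = 0.0665). Its exact permutation p was 0.0286, the smallest that 4 against 4 samples can give. Cre is driven by Pgr in these mice, and an effect of the Cre allele on the Pgr counts was not tested.

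In DKO ovaries the metallothionein genes Mt1 and Mt2 and the matrix gene Vcan fell, and the luteal receptor genes Oxtr and Ptgfr and the lipid enzyme gene Acss2 rose. Slc39a14 (gene ID 213053, chromosome 14, 70303467 to 70351424), a zinc and iron transporter gene, fell from 148 ± 17.1 to 50.7 ± 8.19 CPM (log2 fold change -1.55 ± 0.14, adjusted p = 0.00414). It passed the test in all 23 alternative analyses, among them the 8 that left out 1 library each. Of those 8, Mt1, Mt2 and Vcan passed in 2, 2 and 3, and Oxtr, Ptgfr and Acss2 in 5, 5 and 6. The potassium channel gene Kcnk3 rose from 44.3 ± 15.95 to 191 ± 27.8 CPM (2.11 ± 0.23, adjusted p = 0.00988), and the adrenergic receptor gene Adra1d rose from 4.92 ± 1.22 to 19.8 ± 3.68 CPM (2.01 ± 0.21, adjusted p = 0.00699). Calls in this text are those of edgeR's quasi-likelihood test on all libraries with no block, unless another fit is named. Of 16870 genes tested, 212 passed an adjusted p of 0.05, 128 higher and 84 lower in DKO, and 110 of these differed by more than 2-fold. In all 212 the 4 samples of one group lay above the 4 of the other. Of all tested genes, 9.24% showed such a separation, against 2.86% by chance.

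The largest rise under the rule for named genes was in Cdh15, a cadherin gene, with a log2 fold change of 2.39 ± 0.46 from 1.73 CPM in controls. It was followed by the presynaptic scaffold gene Bsn (2.38 ± 0.34), the prostaglandin F receptor gene Ptgfr (2.36 ± 0.32), and Gsg1l (2.27 ± 0.40). The vesicle transport gene Rab27a (2.20 ± 0.39), Lrrn1 (1.90 ± 0.34) and the phospholipase gene Plcb2 (1.84 ± 0.25) were also among the largest rises, with Kcnk3 and Adra1d. The largest fall was in the secretogranin gene Scg2 (-2.44 ± 0.44), followed by the guanine deaminase gene Gda (-2.39 ± 0.42), the D-lactate dehydrogenase gene Ldhd (-2.27 ± 0.28) and the metallothionein gene Mt2 (-2.17 ± 0.36). The prostaglandin transporter gene Slco2a1 fell from 299 ± 83.3 to 89.6 ± 22.7 CPM (-1.74 ± 0.25). Prune2 (-1.70 ± 0.23), the inflammatory caspase gene Casp4 (-1.65 ± 0.31), the cytokine gene Lif (-1.58 ± 0.30) and Arl4d (-1.57 ± 0.30) fell as well.

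**Figure D1:**
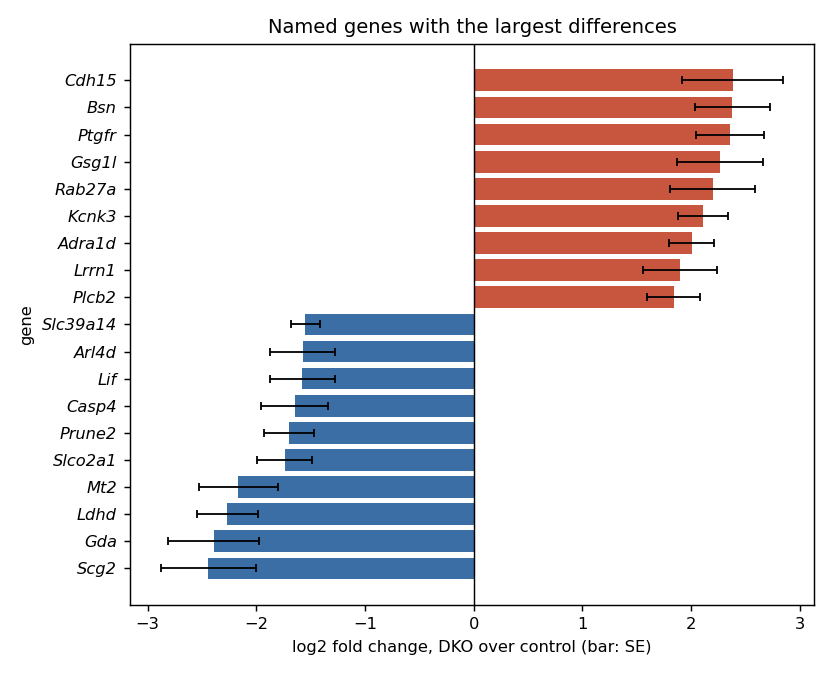
Log2 fold change, DKO over control, of 9 of the 10 genes with the largest rise under the rule for named genes (red) and the 10 with the largest fall (blue); bars are estimates and lines their SE (n = 4 per group). Values run from -2.44 for Scg2 to 2.39 for Cdh15.

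The number of calls depended on single libraries. It was 258, 2, 506 and 27 without controls 1, 2, 3 and 4, and 78, 66, 9 and 113 without DKO 1, 2, 3 and 4. All 212 genes kept their direction in each of these fits. That is no sign of stability, since the groups did not overlap in any of the 212 and leaving out a library could hardly turn them. Of the 33 named genes called with all libraries, 24, 1, 27 and 6 were called without controls 1, 2, 3 and 4, and 14, 15, 3 and 18 without DKO 1, 2, 3 and 4. The call of Fads2 ended with DESeq2 size factors (adjusted p = 0.0526), and those of Fads2, Runx1 and Hsd3b1 ended with non-robust dispersions (0.0535, 0.0548 and 0.0532). With limma-voom Gda (0.0534) and Lif (0.0541) were not called, and with no filter Gsg1l (0.111), Rab27a (0.116), Lrrn1 (0.0972), Gda (0.116), Mt2 (0.0853) and Arl4d (0.0747) were not.

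Of the 34 genes in the list named LH-induced, 30 were below 0, with a median log2 fold change of -0.71. All ovaries were taken after hCG, so whether LH induced each member in these mice was not tested. Camera called this list lower in DKO with a preset correlation (adjusted p = 1.19e-09), but not with an estimated one (adjusted p = 0.425 with an estimated correlation), and its fry adjusted p was 0.169. The metallothionein gene Mt1 fell from 472 ± 193 to 162 ± 20.3 CPM (-1.54 ± 0.25) and Mt2 from 540.3 ± 274 to 120.3 ± 32.5 CPM (-2.17 ± 0.36). The hypoxia-inducible factor gene Hif1a fell from 655 ± 81.9 to 405 ± 46.5 CPM (-0.69 ± 0.13) and the transcription factor gene Runx1 from 347 ± 22.8 to 211 ± 43.9 CPM (-0.72 ± 0.15). These 4 members passed over all genes tested, with adjusted p of 0.0288, 0.035, 0.0414 and 0.0498, and none was called higher (8 lower and 1 higher when adjusted over the list alone).

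Other well-known ovulatory genes did not pass the edgeR test. The protease gene Adamts1 was at 2392 ± 845 CPM in controls and 973 ± 538 in DKO (-1.30 ± 0.46, adjusted p = 0.212), and it was called lower by DESeq2 (0.0224) and by limma-voom with quality weights (0.0384). The prostaglandin synthase gene Ptgs2 was at 308 ± 125 and 117 ± 115 CPM (-1.40 ± 0.97, adjusted p = 0.56). The endothelin gene Edn2 (-1.13 ± 1.23) and the growth factor gene Areg (-1.05 ± 1.01) had adjusted p values of 0.73 and 0.691. The angiogenic factor gene Vegfa was at 235 ± 38.2 and 281 ± 58.5 CPM (0.25 ± 0.17, adjusted p = 0.542).

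Cumulus expansion is the swelling of the matrix between the cells around the oocyte. Of its genes, 12 of 13 were below 0, with a median of -1.02, which was -0.65 without DKO 1 and -1.63 without DKO 4. The matrix proteoglycan gene Vcan fell from 2168 ± 379 to 800.3 ± 282 CPM (-1.44 ± 0.26, adjusted p = 0.035) and was the 1 member called over all genes (3 lower and 1 higher when adjusted over the list alone). The hyaluronan synthase gene Has2 (-1.40 ± 0.85, adjusted p = 0.491) and the hyaluronan matrix genes Ptx3 (-0.97 ± 0.53, 0.441) and Tnfaip6 (-1.02 ± 0.90, 0.659) did not pass. The list was lower by camera (adjusted p = 2.48e-05), but not with an estimated correlation (adjusted p = 0.425 with an estimated correlation). Areg, Ereg, Il6 and Ptgs2 belong to both this list and the LH-induced list.

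**Figure D2:**
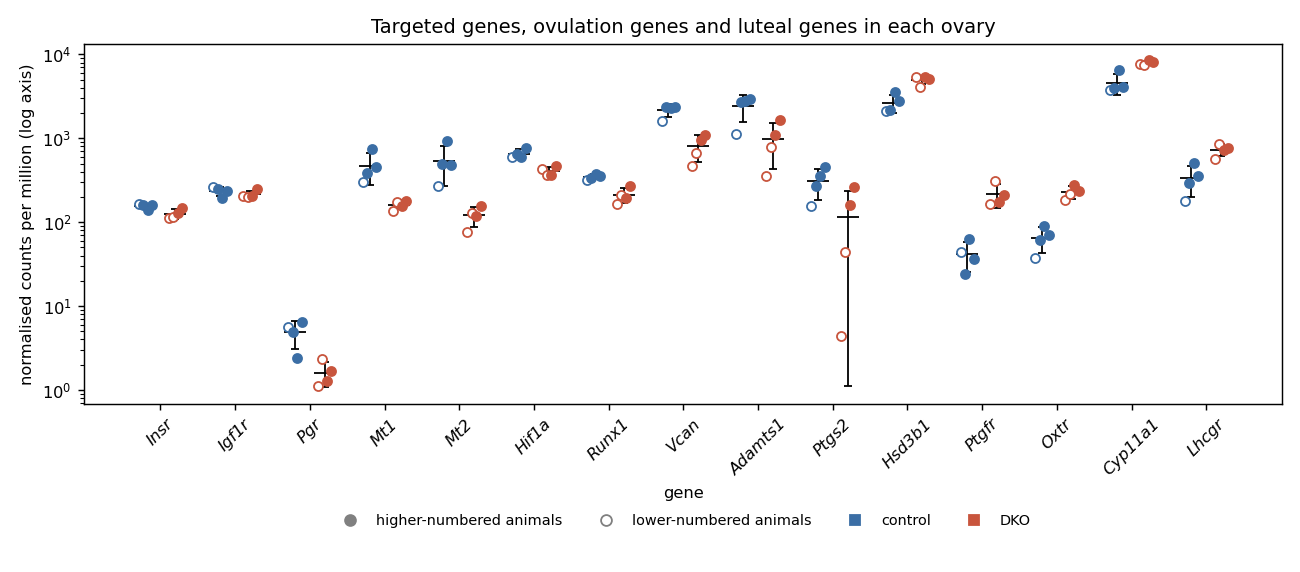
Normalised CPM on a log axis of 15 genes in each of the 8 ovaries, controls in blue and DKO in red, with open symbols for the lower-numbered animals, 167 to 202; horizontal marks are group means and vertical lines SD (n = 4 per group). Mt1, Mt2, Hif1a, Runx1 and Vcan lay lower in all 4 DKO ovaries than in any control, whereas the groups overlapped in Adamts1 and Ptgs2.

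Of 20 genes of luteal differentiation, 4 passed the test and were higher in DKO, and in all 13 lay above 0 and 7 below. The oxytocin receptor gene Oxtr rose from 64.99 ± 21.98 to 229 ± 38.5 CPM (1.82 ± 0.25, adjusted p = 0.0162) and Ptgfr from 42.1 ± 16.7 to 216 ± 66.5 CPM (2.36 ± 0.32, adjusted p = 0.0173). Mgarp, a mitochondrial protein gene of steroid-producing cells, rose by 0.80 ± 0.16 on the log2 scale (adjusted p = 0.0453). Hsd3b1, whose enzyme makes progesterone, rose from 2656 ± 646 to 4999.6 ± 599 CPM (0.91 ± 0.18, adjusted p = 0.0477). No member was called lower over all genes (10 higher and 1 lower, Parm1, when adjusted over the list alone), and the median was 0.52. The LH receptor gene Lhcgr was at 335 ± 138 and 732 ± 121 CPM (1.13 ± 0.28, adjusted p = 0.0893). The list was higher by camera (adjusted p = 9.35e-08), but not with an estimated correlation (adjusted p = 0.425 with an estimated correlation).

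Among 21 genes of steroidogenesis, Hsd3b1 was the 1 member to rise over all genes and none fell (4 higher and 0 lower when adjusted over the list alone), with 15 above 0 and 6 below. Their median was 0.29, and 0.17 without control 1. Cyp11a1, whose enzyme makes the first steroid from cholesterol, was at 4560.5 ± 1280.5 CPM in controls and 7941 ± 479 in DKO (0.80 ± 0.18, adjusted p = 0.0704). Star, which brings cholesterol into mitochondria, was at 2107 ± 729 and 2098 ± 1426 CPM (-0.0068 ± 0.52, adjusted p = 0.997). The aromatase gene Cyp19a1 was at 16.97 ± 10.6 and 22.7 ± 10.7 CPM (0.42 ± 0.54, adjusted p = 0.776). The list was higher by camera (adjusted p = 2.53e-04), but not with an estimated correlation (adjusted p = 0.425 with an estimated correlation).

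Of 16 genes of fatty acid synthesis, 4 passed the test and were higher in DKO, and in all 13 lay above 0 and 3 below. Acss2, which makes acetyl-CoA from acetate, rose from 26.2 ± 2.49 to 52.8 ± 7.16 CPM (1.01 ± 0.12, adjusted p = 0.0122). On the log2 scale the elongase gene Elovl5 rose by 0.86 ± 0.14, and the desaturase genes Fads1 and Fads2 by 0.86 ± 0.17 and 1.04 ± 0.21 (adjusted p = 0.0288, 0.0451 and 0.049). No member was called lower over all genes (9 higher and 0 lower when adjusted over the list alone), and the median was 0.39. The list was higher by camera (adjusted p = 1.77e-08), but not with an estimated correlation (adjusted p = 0.227 with an estimated correlation). With fry, which asks whether members move one way on balance, its adjusted p was 0.0188, the only one of the 29 lists under 0.05. That p was 0.0513, 0.0707 and 0.0528 without controls 1, 2 and 3, and 0.0539, 0.0823 and 0.0564 without DKO 2, 3 and 4.

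In cholesterol synthesis 24 of 25 members were above 0, with a median of 0.37 (0.23 without DKO 4), but none passed the edgeR test over all genes or when adjusted over the list alone. DESeq2 called 2 higher (Hmgcs1 and Dhcr7) and limma-voom with quality weights 6. Dhcr7, whose enzyme makes cholesterol in the last step of the pathway, had the smallest adjusted p (295 ± 73.4 and 516 ± 130.3 CPM, 0.81 ± 0.21, adjusted p = 0.108). The list was higher by camera (adjusted p = 1.50e-05), but not with an estimated correlation (adjusted p = 0.626 with an estimated correlation).

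**Figure D3:**
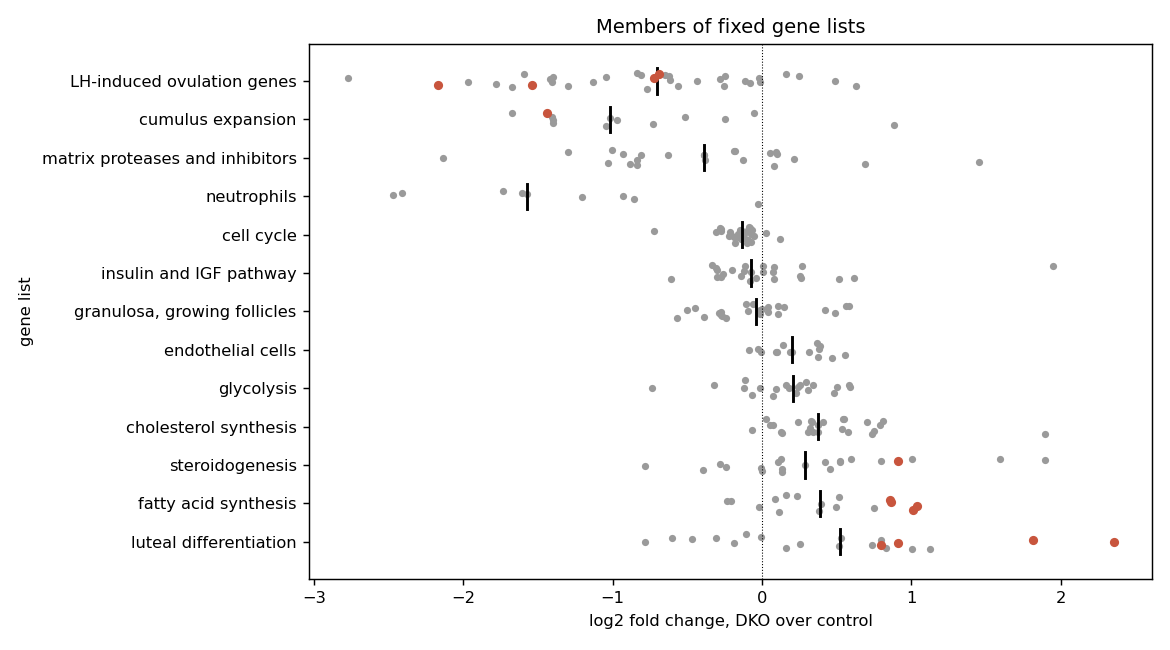
Log2 fold change, DKO over control, of the tested members of 13 gene lists; red points passed an adjusted p of 0.05 over all genes, grey points did not, vertical marks are medians, and points are spread vertically for legibility. Medians run from -1.58 for neutrophil genes to 0.52 for luteal genes.

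Another 7 lists were called by camera with the preset correlation although no member passed the edgeR test over all genes. Lower in DKO were matrix proteases and inhibitors (23 tested, median -0.39, adjusted p = 2.83e-04), neutrophil markers (9 tested, -1.58, 2.93e-04) and immediate early genes (18 tested, -0.63, 5.69e-04). Smooth muscle markers (11 tested, -0.46, 0.0016) and cell cycle genes (29 tested, -0.14, 0.00814) were lower too. Higher were endothelial markers (15 tested, 0.20, 0.00519) and glycolysis genes (20 tested, 0.21, 0.0392). The adjusted p with an estimated correlation was 0.425 for matrix proteases and for neutrophils, 0.633 for immediate early genes and 0.626 for the rest. Adjusted over the list alone, S100a8, S100a9 and Il1b of the neutrophil list were lower, Pfkm and Pgam1 of glycolysis were higher, and no member of the other 5 lists passed.

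In these 7 lists the members with the smallest adjusted p were Mmp19 (-1.003 ± 0.25, 0.101) for proteases, Il1b (-1.74 ± 0.49, 0.126) for neutrophils, Fosl1 (-1.86 ± 0.49, 0.12) for immediate early genes and Des (-0.75 ± 0.26, 0.198) for smooth muscle. They were Rrm2 (-0.72 ± 0.19, 0.103) for the cell cycle, Tie1 (0.39 ± 0.12, 0.157) for endothelium and Pgam1 (0.50 ± 0.11, 0.0658) for glycolysis. The call of glycolysis ended without control 2, control 4, DKO 1 or DKO 2 (camera adjusted p = 0.0656, 0.129, 0.115 and 0.159) and with the stricter filter (0.0581). Its median was 0.13 without DKO 1 or without DKO 2 and 0.31 without DKO 3. The call of the cell cycle ended without control 2, control 3 or DKO 2 (0.0522, 0.0506 and 0.0752), and that of endothelium without DKO 4 (0.0907). The endothelial median was 0.35, 0.13 and 0.052 without DKO 1, 3 and 4, the immediate early median -0.37 without control 4, and the neutrophil median -0.97 with quality weights. With the run of animal numbers, described below, as a block, glycolysis (0.126) and the cell cycle (0.0619) were not called. DESeq2 called members of 5 of these lists, lower for Adamts1, Mmp19, Plaur and Ctsl of the proteases, S100a8, S100a9 and Il1b of neutrophils, Fosl1 of the immediate early genes and Rrm2 of the cell cycle, and higher for Gpi1, Pfkm and Pgam1 of glycolysis. Quality weights called 5 proteases, Fosl1 and Rrm2 lower, 4 endothelial genes higher (Kdr, Tek, Tie1 and Egfl7), and 5 glycolysis genes higher and 1 lower.

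The insulin and IGF pathway had no called member among 25 in the edgeR fit of all libraries with no block. DESeq2 called Insrr and Igfbp2 higher, quality weights called 2 higher and 3 lower (Irs1, Irs2, Igfbp2, Igfbp4 and Foxo1 in all), and edgeR with no filter called Igfbp2 higher (0.0371). Its median was -0.073, its mean 0.038 and its camera direction down (adjusted p = 0.869, and 0.93 with an estimated correlation). The binding protein gene Igfbp2 was at 59.9 ± 10.2 and 91.7 ± 8.46 CPM (0.61 ± 0.13, adjusted p = 0.0592) and was the 1 member higher when adjusted over the list alone. FOXO targets (21 tested, median -0.13, camera adjusted p = 0.102) had no called member in that edgeR fit, and the catalase gene Cat had the smallest adjusted p (0.40 ± 0.088, 0.0655). Adjusted over the list alone, Cat and Cdkn1b were higher and Pdk4 lower. DESeq2 called 2 FOXO targets higher and 2 lower (Cdkn1b, Pdk4, Cat and Ccn2), quality weights 2 and 4, and edgeR with library size only, upper quartile factors or the stricter filter called Cat (0.0377, 0.0418 and 0.0488). Granulosa genes of growing follicles (24 tested, median -0.038, 0.835) had no called member either, and Foxl2 (0.58 ± 0.13, adjusted p = 0.0716) was the 1 member higher over the list alone. In the hypoxia response (18 tested, median -0.057, 0.102), Ndrg1 (-0.88 ± 0.18, adjusted p = 0.0552) was the 1 member lower over the list alone. Apoptosis and atresia genes (19 tested) had a median of -0.024, a mean of 0.034 and camera direction up (adjusted p = 0.733), and Tnfrsf10b (0.96 ± 0.22, adjusted p = 0.0708) was the 1 member higher over the list alone. With the run of animal numbers as a block, Igfbp2 (0.56, adjusted p = 0.0374), Cat (0.41, 0.0426), Ndrg1 (-0.79, 0.0377) and Tnfrsf10b (1.05, 0.0117) passed over all genes, and the FOXO target Sod2 was called higher. DESeq2 and quality weights called Foxl2, Ndrg1 and Tnfrsf10b as well (DESeq2 adjusted p = 0.00414, 6.43e-04 and 0.00239). Camera with the preset correlation called FOXO targets lower within animals 249 to 263 (median -0.31, adjusted p = 0.00694), without control 1 and DKO 2 (0.00333) and without control 1 (0.00522). It called the hypoxia response lower within animals 249 to 263 (median -0.18, 6.64e-04), without control 1 and DKO 2 (0.00603), without DKO 1 and DKO 2 (0.00107) and without DKO 2 (0.00569), and granulosa genes lower with quality weights (0.0202). None of these list calls held with an estimated correlation where that was run (adjusted p of 0.133 or more with an estimated correlation).

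In 3 further lists 1 member each was called over all genes while camera did not call the list. The clock repressor gene Nr1d1 rose from 18.6 ± 6.15 to 40.9 ± 6.74 CPM (1.13 ± 0.22, adjusted p = 0.0429). The circadian list (15 tested) had a median of -0.058, a mean of 0.14 and camera direction up (adjusted p = 0.539), with 3 higher and 1 lower when adjusted over the list alone. The tight junction gene Cldn1 fell from 30.5 ± 2.83 to 12.2 ± 3.24 CPM (-1.32 ± 0.18, adjusted p = 0.0162) in a list of 12 (median -0.0096, camera adjusted p = 0.472), with 1 higher and 1 lower over the list alone. The lipid droplet gene Plin1 rose from 10.6 ± 2.50 to 25.2 ± 4.45 CPM (1.25 ± 0.20, adjusted p = 0.0277) in the fat pad list. There 10 of 13 members were below 0 (median -1.04, camera adjusted p = 0.118), with 3 higher and 2 lower over the list alone. Camera called the fat pad list lower with no filter (0.0161), within animals 249 to 263 (0.0012), without control 1 and DKO 2 (5.45e-04), without DKO 1 and DKO 2 (0.00533), and without control 2 (0.0164), DKO 2 (1.67e-04) or DKO 4 (0.0457), but not with an estimated correlation (adjusted p of 0.218 or more with an estimated correlation).

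Markers of 8 other cell types had no called member, and camera called none of these lists, in the edgeR fit of all libraries with no block. DESeq2 called Lhcgr of theca and Hba-a1 and Hba-a2 of the erythroid list higher and Cd14 of macrophages lower (0.00146 for Lhcgr, 0.0203 for Hba-a2 and 0.0058 for Cd14), and quality weights called Lhcgr higher (0.00502) and Hhip lower. The oocyte list had a median of -0.34 (21 tested, adjusted p = 0.0646), with the oocyte growth factor gene Gdf9 at 81.9 ± 39 and 61.7 ± 32.6 CPM (-0.41 ± 0.50, adjusted p = 0.767). Medians were 0.027 for theca (11 tested, 0.406), -0.12 for stroma (12 tested, 0.685) and -0.15 for macrophages and monocytes (15 tested, 0.0704). They were 0.091 for lymphocytes (10 tested, 0.63) and 0.63 for erythroid genes (9 tested, 0.159). Surface epithelium had a median of -0.18 with camera direction up (14 tested, 0.763), and oviduct epithelium a median of -0.45 (13 tested, 0.644). The smallest adjusted p in these lists belonged to Lhcgr in theca, Lum (0.39, 0.332) in stroma, Cd14 (-1.20, 0.102) in macrophages and Oosp1 (-0.37, 0.524) in oocytes. In the rest it belonged to Gzma (1.33, 0.145), Hba-a2 (0.83, 0.145), Aldh1a2 (0.53, 0.367) and Krt20 (-0.45, 0.434). Adjusted over the list alone, Lhcgr was higher among theca genes, Cd14 lower among macrophage genes, and Hba-a1, Hba-a2 and Alas2 higher among erythroid genes. Some of these lists were called by camera with the preset correlation under other settings. Oocyte markers were called lower with no filter (0.0244), quality weights (0.0123), without control 1 and DKO 2 (4.67e-04), and without control 1 (2.58e-05) or DKO 3 (3.06e-05). Macrophage markers were called lower with no filter (0.0438) and without control 2 (0.0225), control 3 (0.042) or DKO 3 (0.0182). Oviduct epithelium was called lower with the run as a block (0.0405), without DKO 1 and DKO 2 (0.00509) and without DKO 2 (0.00456). Within animals 249 to 263, surface epithelium (median 0.35, 0.00413), erythroid genes (0.00342) and theca genes (0.0371) were called higher. Surface epithelium was also higher without control 1 and DKO 2 (median 0.44, 2.31e-04) and without control 1 (median 0.84, 4.31e-05). Erythroid and theca genes were also higher without DKO 1 and DKO 2 (7.10e-05 and 0.0195), and erythroid genes without DKO 1 (4.92e-04). None of these calls held with an estimated correlation where that was run (adjusted p of 0.235 or more with an estimated correlation).

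The 8 libraries also differed along lines other than genotype. The numbers in the sample titles, taken here as animal numbers, fell into one run from 167 to 202 (control 1, DKO 1 and DKO 2) and another from 249 to 263 (controls 2 to 4, DKO 3 and DKO 4). The first principal component, with 38.3% of the variance, separated these runs. The oviduct gene Ovgp1 was at 1214 CPM in control 1 and 742 in DKO 2, against 2.52 to 22.5 elsewhere. The 18S ribosomal RNA gene Rn18s-rs5 reached 24452 and 23229 CPM in DKO 1 and DKO 2, against 1130.3 to 2626 elsewhere. The mitochondrial ribosomal RNA genes mt-Rnr1 (211 ± 27.4 CPM in controls, 559.6 ± 266 in DKO, adjusted p = 0.0716) and mt-Rnr2 (231 ± 27.9 and 931 ± 664 CPM, adjusted p = 0.108) lay above every control in all 4 DKO libraries. The mitochondrial share of counts, made up of ribosomal and transfer RNA, was 0.0461 ± 0.00418% in controls and 0.153 ± 0.0951% in DKO (mean ± SD, n = 4 each). It thus moved with genotype, as did the medians of the LH-induced, cumulus, luteal, steroid, fatty acid and cholesterol lists. With the run as a block, 526 genes were called (307 higher and 219 lower), all 212 among them. Within animals 249 to 263 (3 controls and 2 DKO), 169 were called (103 higher and 66 lower), 75 of them shared with the 212. The run from 167 to 202 held 1 control and was too small to test alone. Without control 1 and DKO 2, 97 genes were called, and without DKO 1 and DKO 2, 64 (53 higher and 11 lower).

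Between the runs, adjusted for group, the LH-induced list differed by a median of -0.68 with 13 members lower in animals 167 to 202, and the cumulus list by -1.41 with 7 lower. Immediate early genes (-1.44, 16 of 18 lower) and oocyte markers (-1.25, 16 of 21 lower) differed too, as did surface epithelium (1.56, 11 higher) and oviduct epithelium (2.72, 10 higher). With an estimated correlation no list passed camera between the runs (adjusted p = 0.211 for LH-induced genes, 0.167 for cumulus genes and 0.157 for immediate early genes, the smallest). With the block, the LH-induced list had 7 members lower and 1 higher (median -0.66), and Pgr, Snap25 and Zbtb16 were called lower along with Mt1, Mt2, Hif1a and Runx1. Within animals 249 to 263 it had 5 lower (median -0.46), which were Snap25, Zbtb16, Prkg2, Mt1 and Mt2. Its median was -0.70 with 2 members lower without control 1 and DKO 2, and -0.33 with 0 called without DKO 1 and DKO 2. Vcan was called with the block and within animals 249 to 263, but not without control 1 and DKO 2 (adjusted p = 0.0607) or without DKO 1 and DKO 2 (0.0952). The cumulus median was -0.60 within animals 249 to 263 and -0.54 without DKO 1 and DKO 2. Of the luteal genes 7 were higher with the block, Lhcgr and Cyp11a1 among them, 2 within animals 249 to 263 (Ptgfr and Oxtr), 2 without control 1 and DKO 2 and 1 without DKO 1 and DKO 2. The luteal median was 0.34 within animals 249 to 263. Of the steroidogenesis genes 4, 1, 0 and 0 were higher in these 4 fits, and the 1 within animals 249 to 263 was Hsd17b7. Hsd3b1 was called with the block but not in the other 3 fits (adjusted p = 0.13, 0.0751 and 0.141), and the steroidogenesis median was 0.45 without DKO 1 and DKO 2. Of the fatty acid genes 6, 3, 1 and 3 were higher in the 4 fits, Acss2 in each. Of the cholesterol genes 5, 4, 0 and 2 were higher, with Hmgcs1 among them wherever any was called, and their median was 0.66 within animals 249 to 263 and 0.72 without DKO 1 and DKO 2. The median of the immediate early list was -0.39 with the block, -0.25 within animals 249 to 263 and -0.025 without DKO 1 and DKO 2 (camera adjusted p = 0.888 in the last). In these 3 fits the endothelial median was 0.31, 0.38 and 0.44, and the glycolysis median 0.12, 0.020 and -0.015. Glycolysis was not called in any of the 4 fits (camera adjusted p = 0.126, 0.674, 0.0977 and 0.892), nor the cell cycle without DKO 1 and DKO 2 (0.0684).

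**Figure D4:**
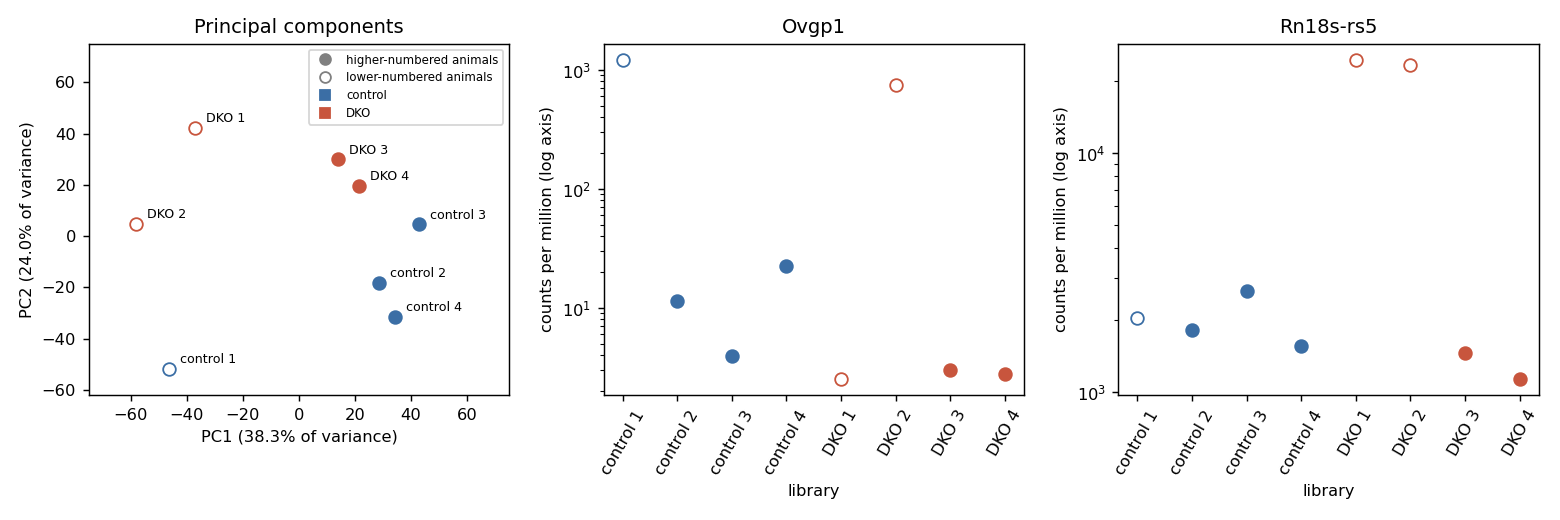
Left, the first 2 principal components of log2 CPM; middle and right, CPM of the oviduct gene Ovgp1 and the 18S ribosomal RNA gene Rn18s-rs5 in each library on log axes, controls in blue, DKO in red, open symbols for the lower-numbered animals, 167 to 202. Ovgp1 was at 1214 CPM in control 1 and 742 in DKO 2, and Rn18s-rs5 at 24452 and 23229 CPM in DKO 1 and DKO 2.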

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

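The rule for samples standing apart was fixed before the data were seen, though measures of the libraries it was applied to were chosen afterwards, and apart from the count of neighbouring called genes the other tests were chosen only after the results they address had been seen.

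A sample counted as standing apart when its gap to the nearest of the other 3 in its group exceeded Dixon's 95% critical share of the group's range. This held in 13 of 156 groups of values (8.33%), where chance gives about 5%. Control 1 was low for Vcan (1602 CPM), Adamts1 (1137 CPM) and Star (1016 CPM), and high for Aldh1a2 (67.4 CPM) and Ovgp1 (1214 CPM). Its share of Hbb-b1 and Hbb-b2 in beta globin counts was 61.0% (95% exact binomial interval 60.2 to 61.9, counting error only), against 0.199% (0.131 to 0.290) in control 2 to 0.36% (0.251 to 0.4998) in control 4. Control 3 was high for Adra1d (6.74 CPM), Cyp11a1 (6472 CPM) and total count (37.6 M counts). DKO 1 was low for Slco2a1 (55.6 CPM) and high for Cat (158 CPM), DKO 2 was high for Ovgp1 (742 CPM), and DKO 4 was high for Igf1r (247 CPM).

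The LH-induced list had a median of -0.71 and 4 members called lower in DKO, and camera called it lower with the preset correlation but not with an estimated one (adjusted p = 0.425 with an estimated correlation). The tables argue against the runs of animal numbers as the whole cause, since with the run as a block 7 members were called lower and the median was -0.66, although the runs differed in this list about as much as the groups (median -0.68, 13 members lower in animals 167 to 202). They also argue against oviduct tissue in control 1 and DKO 2 as the whole cause, since the median was -0.70 without both libraries, although 2 members rather than 4 were then called lower. Each group held 1 of these libraries, so leaving out both was a weak test. Libraries DKO 1 and DKO 2 as the whole cause are argued against by the fit within the higher-numbered run, which also lacks them. There 5 members were called lower, Mt1 and Mt2 among them, and the median was -0.46. The list did not pass camera with an estimated correlation there (adjusted p = 0.301). A part played by DKO 1 and DKO 2 stays open. Without these libraries alone the median was -0.33 and no member was called. That fit keeps control 1, whose mean log2 CPM over the list was 5.99, against 6.60 to 6.89 in the other controls. Both fits had only 2 DKO libraries left. The loss of the receptors, and a different time course after hCG in these animals, remain untested biological explanations.

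Transcripts of histone genes picked by symbol as replication-dependent, a set chosen after its values were seen, were higher in DKO. Of 63 such genes found, 9 passed the filter and were tested, so nothing is known here of the rest. Over these 9 the summed level was 52.9 ± 7.46 CPM in controls and 107 ± 14.2 in DKO, and H2bc21 and H2bc4 were called. The exact permutation p of 0.0286, the smallest possible, restates the choice of the set and is no separate support. Most of the sum came from H2bc4 (24.2 CPM in controls and 42.5 in DKO), H1f2 (16.1 and 33.7) and H2bc21 (9.62 and 24.9). The other members had means of at most 2.51 CPM. Whether the transcripts counted carry poly(A) tails, or depend on replication, was not tested. Carry-over of RNA without poly(A) tails stays open: DKO 3 and DKO 4 had 18S ribosomal RNA below every control, the 7SK RNA gene Rn7sk at 2.62 and 2.49 CPM within the range of controls (1.96 to 4.97) and histone sums of at least 94.3 CPM, against at most 62.4 in controls, but their mitochondrial ribosomal RNA was above every control (mt-Rnr2 at 364 and 359 CPM, against at most 255). More cells in S phase is argued against by 11 S phase genes, whose median was -0.16 with an SD of 0.20, against 1.02 for the histone genes. Reads shared between near-identical histone copies were not tested, so the origin of the difference stays open.

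Of the 35 splits of the 8 samples into 4 and 4, the real one alone gave as many as 212 calls, and the highest of the others gave 4. That is the smallest share that 35 splits can give. The other splits mix both groups on each side, so any difference between groups or libraries widens their spread. Their counts are thus no null for the 212 calls, and chance is not excluded. DNA within 20 Mb of the floxed genes as the whole cause is argued against by position. Of 283 tested genes there, 2 were called (0.707%, Plin1 among them) against 1.27% elsewhere (Fisher's exact test, two-sided p = 0.59). With so few calls the test cannot tell whether such DNA played a part, and it does not cover DNA further away. Linked strain variants along chromosomes stay open, since the beta globin forms differed between animals labelled as 1 strain. Within 1 Mb of each other lay 39 pairs of successive called genes, against a median of 31 in 10000 random draws of as many tested genes (one-sided p over the draws = 0.0771). The pairs include neighbours of one gene family, such as Mt2 with Mt1, Fads2 with Fads1 and Adh7 with Adh1. The draws did not allow for such neighbours, so the count cannot decide the question. The number of calls without 1 library was 258, 2, 506 and 27 for controls 1 to 4 and 78, 66, 9 and 113 for DKO 1 to 4.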

How the results depend on the processing

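The block of animal numbers, the fit within animals 249 to 263 and the fits without pairs of libraries were chosen after seeing the data, and the other alternatives were planned. All 212 genes kept their direction in every alternative that tested them. In the fits that leave out libraries this was all but fixed in advance, since the groups did not overlap in any of the 212. The count stayed within 1.5 times of 212 with 3 other scalings, 2 other filters, limma-voom and non-robust dispersions (184 to 246), and 12 to 18 of the 29 lists were called by camera with the preset correlation wherever lists were tested, and 0 wherever the correlation was estimated. DESeq2 called 1107 (636 higher, 471 lower), limma-voom with quality weights 1651 (996 and 655) and the replicate block 743 (361 and 382). Correlations between samples of the same number ran from -0.359 to 0.468, with 3 of 4 above 0.1. Of the 8 samples, 5 correlated best with their own number. The 3 pairs above 0.1 lay within a run of animal numbers, and the pair at -0.359, control 2 and DKO 2, lay across the runs. Over all pairs of a control and a DKO sample, correlations were 0.116 to 0.638 within a run and -0.475 to 0.0607 across runs. They thus followed the runs and cannot tell a pairing by number from them. As not every pair was above 0.1, the numbers were not taken to pair samples. With the replicate block Ptgfr (0.0534), Lrrn1 (0.0647) and Fads2 (0.0673) were not called, Adamts1 (0.0105), Has2 (0.0318) and Ptx3 (0.0295) were, and the LH-induced list had 14 members lower and 1 higher. A test against 1.5-fold called 5 (3 and 2), as its stricter null implies. The animal number block called 526 (307 and 219), the fit within animals 249 to 263 called 169 (103 and 66), that without control 1 and DKO 2 called 97 (49 and 48), and that without DKO 1 and DKO 2 called 64 (53 and 11). Leaving out 1 library gave 2 to 506 (1 to 339 higher, 1 to 167 lower): 258, 2, 506 and 27 without controls 1 to 4, and 78, 66, 9 and 113 without DKO 1 to 4. Where all libraries were kept, the cause was not tested. Depth limits what can be seen of rare transcripts, since 3 counts were 0.0764 to 0.0905 CPM in a library.

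Some values not called changed sign. Star was at 0.011 with library size only, 0.018 with no filter, 0.19 with the animal number block, 0.45 within animals 249 to 263, 0.030 without control 1 and DKO 2 and 0.68 without DKO 1 and DKO 2, and from -0.34 to 0.26 leaving out 1 library. Gdf9 was at 0.044 with the block and 0.094 without DKO 1 and DKO 2, Cyp19a1 at -0.10 with quality weights, and Igf1r at 0.014 within animals 249 to 263. The immediate early list, which camera called lower in the main analysis with the preset correlation but not with an estimated one (adjusted p = 0.633 with an estimated correlation), had a median of -0.025 without DKO 1 and DKO 2, and its camera direction turned there. The glycolysis median was -0.015 in that fit. Between the runs of animal numbers, adjusted for group, Star (-1.65, adjusted p = 0.00395) and Gdf9 (-1.53, 0.00934) were lower in the lower-numbered run. The immediate early median between the runs was -1.44, with 16 of 18 members lower. The values of Star, Gdf9 and this list thus shift with the balance of the runs in a fit. Cyp19a1 (-0.79, 0.433) and Igf1r (0.0012, 0.996) did not pass between the runs, and the glycolysis median was 0.18. The cause of the other changes was not tested.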

Other observations

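All genes and tests in this part were chosen after their values were seen.

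Besides Mt1 and Mt2, the metallothionein gene Mt3 fell, from 15.4 ± 4.53 to 5.69 ± 1.39 CPM (log2 fold change -1.44 ± 0.25, adjusted p = 0.0328). The glutamine synthetase gene Glul fell from 1158 ± 250.2 to 575 ± 81.3 CPM (-1.01 ± 0.17, adjusted p = 0.0328) and the secreted protein gene Crispld2 from 1184 ± 171 to 468 ± 164 CPM (-1.34 ± 0.24, adjusted p = 0.0344). The mast cell protease genes Tpsb2 (-1.79 ± 0.34, adjusted p = 0.0425) and Cpa3 (-1.66 ± 0.33, adjusted p = 0.0482) fell from low levels of 1.49 and 0.984 CPM.

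The retinol saturase gene Retsat rose from 16.5 ± 1.48 to 36.8 ± 4.58 CPM (1.16 ± 0.13, adjusted p = 0.00931), and the alcohol dehydrogenase genes Adh1 and Adh7 rose by 1.02 ± 0.19 and 1.13 ± 0.20 on the log2 scale (adjusted p = 0.0374 and 0.0352). The endothelial lipase gene Lipg rose from 133 ± 28.03 to 385 ± 103 CPM (1.53 ± 0.21, adjusted p = 0.0162). The fatty acid oxidation genes Acaa2 (0.60 ± 0.092, adjusted p = 0.0227) and Echs1 (0.54 ± 0.10, 0.0447), the ketone body gene Bdh1 (0.90 ± 0.14, 0.0255) and the pyruvate carboxylase gene Pcx (0.87 ± 0.16, 0.0425) rose as well.

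The share of Hbb-b1 and Hbb-b2 in beta globin counts was 99.8% in DKO 1 (95% exact binomial interval, counting error only, 99.79 to 99.90), 99.9% in DKO 2 (99.86 to 99.93), 60.3% in DKO 3 (59.8 to 60.9) and 0.244% in DKO 4 (0.178 to 0.326). The labels give C57BL/6 for all 8 animals, a strain that carries Hbb-bs and Hbb-bt instead, so these shares bear on that label, and whether the background differed between the groups was not tested. Between the runs of animal numbers, adjusted for group, 1377 genes were called, 634 higher and 743 lower in animals 167 to 202, and 14 of these were also called between the groups.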
